A study of Mus musculus and Xenopus laevis with 7 samples.

How the data were processed

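Droplet single-cell RNA sequencing libraries (10x Chromium, 3' chemistry per the labels' protocols) of cultured mouse and Xenopus laevis limb explants were read from the deposited tables. The series holds 7 libraries, 5 of mouse and 2 of Xenopus, and each is a group of its own. The deposited values are UMI counts per gene and cell, without normalization. Per the submitters' processing notes, reads were processed with Cell Ranger 8.0.1, and the build GRCm39 is listed for all 7 samples. The build for Xenopus is not given in the sources used here. Each combined table holds the cells that the submitters kept, from 2 or 3 libraries, and the barcodes of each library within it were matched to that library's own list. How those cells were chosen is not recorded. The kept cells have over 500 and under 6000 genes, under 30000 UMIs and under 5% mitochondrial UMIs. The Xenopus library at the air-liquid interface was read from the combined table alone, and 1 Xenopus gene without a usable name is not analysed here.

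Of 46363 barcodes, 32168 were kept, with 407015112 UMIs. The kept share was 38.9% and 55.4% in mouse at 1 dpa (interface, plate), 76.6%, 78.8% and 58.8% at 3 dpa (vehicle, cocktail in the plate, cocktail at the interface), and 79.3% and 86.01% in Xenopus (interface, plate). Kept UMIs in the same order were 34642984, 45379146, 24518800, 30647959, 70776626, 101016494 and 100033103. The median mitochondrial share per cell was 3.33%, 1.91%, 1.33%, 1.74%, 3.36%, 1.95% and 1.23%. Xenopus laevis has 2 copies (homeologs, .L and .S) of many genes, which were summed under 1 name, taking 34365 entries to 27019 names; of 544 genes in the lists, 451 were found in Xenopus and 533 in mouse.

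Cells were clustered per combined table with scanpy 1.11.5 and anndata 0.12.19 in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0): scaling to 10000 counts per cell, log transformation, 2000 variable genes ranked within libraries, 30 principal components, 15 neighbours, and Leiden clusters at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9). No integration across libraries was made, since each group is 1 library. Clusters were named from marker lists by the mean score of their markers against the median cluster, and a class joins the clusters of 1 name. A class other than connective tissue needed a score of 2.5, with exceptions down to 1.5; connective tissue is the name left for the other clusters if their connective score was above -1, and tendon and pericyte markers did not count against it. These limits were set after the data were seen. Class names end in -like because the labels give no cell types. Figures were drawn with matplotlib 3.10.9.

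Comparisons, gene lists and the rule for naming genes were fixed before the data were examined. There were 4: air-liquid interface against 96-well plate in mouse and in Xenopus at 1 dpa, cocktail against vehicle in 96-well plates at 3 dpa, and cocktail at the interface against cocktail in the plate at 3 dpa. The last pair shares the library with cocktail in the plate, so these comparisons are not independent. UMIs were summed over the cells of a class in a library and divided by the class total to give CPM, and the log2 ratio was taken between libraries. A library below 3 UMIs of a gene was set to 3 for the ratio, so that list medians hold such genes at their bound. Intervals of CPM are exact Poisson intervals, those of ratios are exact conditional ones, and those of shares are Clopper-Pearson, all at 95%. Values are rounded to 3 significant digits and log2 values to 2 decimals, with a further digit where the rounded value would equal a setting. With 1 library per group no test across replicates exists, cells of a library are not replicates, and counts of changed genes are not given.

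The 33 gene lists cover oxygen and metabolism, limb and epithelial programs, cell cycle, matrix, signalling, stress, differentiation, chromatin, cholesterol synthesis and markers of other cell types. A member was measured with at least 20 UMIs over both libraries, and a median needed at least 3 members. Each list was set against 10000 random lists of the same size drawn from genes in the same of 20 bins of expression, and a list is called outside their range beyond the central 95%. The genes named by size of ratio are the 6 largest and 6 smallest ratios per comparison and class among genes with at least 50 UMIs in the higher library and at least a 2-fold ratio, leaving out mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and gene models without an approved name. From each list, the up to 4 members with the largest absolute log2 ratio may be named, and Fgf8 and the oxygen sensing genes were read in every library. Some genes that these rules select are not reported here. Other list members named in the text, and genes seen in at least 10% of cells, were chosen after their values were seen. Fgf8 shares were counted after each cell had been thinned at random to the depth of the 10th percentile of epithelial-like cells, in steps of 500 UMIs. Mouse cells were read without thinning for Fgf8 after this depth was seen to be too low.

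The steps were tested on simulated data made from the mouse comparison at 1 dpa in connective tissue-like cells (14365 genes). Of 50 genes each set 2-fold, 4-fold and 8-fold apart, 29, 50 and 50 passed 2-fold in the right direction, and of 50 set 1.5-fold apart 27 passed 1.5-fold. The 95% interval, of counting error alone, held the true ratio for 95.3% of unchanged genes. With counting error alone, all 100 simulated lists with every member 1.5-fold higher fell outside the random range, as did 8 of 100 unshifted ones. Error rates of real lists are not shown.

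Alternatives tried were cells chosen by own thresholds from the per-library tables (at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs; mouse), all kept cells without classes, Leiden resolutions of 0.5 and 2, and scaling by the median ratio of genes or by a total without mitochondrial, ribosomal protein and haemoglobin genes. Further ones were only those connective tissue clusters that scored highest for it (above 0, and without more top markers of another class), each cell weighted equally, another low-count filter, cells thinned to a fixed UMI number, doublet removal with Scrublet as run in scanpy, each Xenopus homeolog alone, and other definitions of the Fgf8 share and of the correlations. The libraries' own tables serve the own thresholds alone, and images, reads and genome coordinates were not used here.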

Results

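Limb explants of wild-type CD-1 mice and of Xenopus laevis, a frog that can regrow limbs at larval stages, were cultured after amputation and profiled by droplet single-cell RNA sequencing. The title of the series names oxygen sensing that differs between species, at the start of limb regeneration, as its subject. Explants were kept in 96-well plates or at an air-liquid interface, where the tissue borders on air. Both formats were sampled in both species at 1 day post-amputation (dpa), with 5 to 6 explants pooled per library. At 3 dpa, mouse explants in 96-well plates had received a cocktail or its volume-matched vehicle, and the cocktail had also been given at the air-liquid interface. The cocktail held BMP4, FGF10 and EGF at 100 ng/mL each and CHIR99021 at 3 µM, a GSK3 inhibitor that turns on Wnt signalling. Per the labels it is meant to induce an apical ectodermal ridge (AER), the epithelial ridge at the limb bud tip whose FGF8 drives outgrowth.

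Each of the 7 groups was 1 library, so there are no replicates, no p-value is given, and every difference below is a difference between libraries. The submitters kept 32168 cells. At 1 dpa these were 2163 mouse cells at the air-liquid interface (median 17937 UMIs per cell) and 3006 in the 96-well plate (16425.5). The Xenopus cells numbered 7931 (12606) and 8601 (10960.0). At 3 dpa there were 2881 cells with vehicle (7898), 2952 with cocktail in the plate (9820.5) and 4634 with cocktail at the interface (15339). Expression is given as UMIs per 1000000 UMIs of a class of cells in a library (CPM). Kept UMIs per library ran from 24518800 (mouse, vehicle) to 101016494 (Xenopus, interface). Brackets hold exact 95% intervals, Poisson for CPM and Clopper-Pearson for shares, which cover counting error alone. A gene list is described by its members at least 1.5-fold higher or lower, its median log2 ratio, and the percentile of that median among 10000 random lists of genes of like expression.

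Most cells lay in clusters called connective tissue-like, the name left where no other class scored high enough. Their share ran from 56.1% with vehicle at 3 dpa to 77.3% in mouse at the air-liquid interface at 1 dpa. In mouse (1 and 3 dpa), connective tissue markers together reached 622 and 926 CPM in clusters of other types outside cartilage and tendon. In unnamed clusters they reached 3254 and 6366 CPM. They were at no less than 2210.5 and 1338 CPM in connective tissue-like clusters, whose naming used them, so the gap is no test. Many of these clusters scored as high or higher for tendon, pericytes or cartilage: those that scored highest for connective tissue (best-scoring clusters below) held 55.3% and 34.2% of the class in mouse at 1 dpa (interface, plate), 26.0% and 23.9% in Xenopus, and 50.9%, 52.5% and 65.3% at 3 dpa (vehicle, cocktail in the plate, cocktail at the interface). Epithelial-like cells were few: 26 and 75 in mouse at 1 dpa (interface, plate) and 293 and 339 in Xenopus. At 3 dpa they were 103, 112 and 65, in the order above. Unnamed cells made up 4.44% and 5.75% in mouse at 1 dpa and 8.10% and 9.70% in Xenopus. At 3 dpa they made up 32.3%, 19.6% and 5.39%, in the same orders. The median log2 ratio over all genes with at least 50 UMIs was 0.16 for mouse connective tissue-like cells at 1 dpa. It was -0.24 and -0.15 for connective tissue-like and epithelial-like cells with cocktail against vehicle, and 0.10 for epithelial-like cells with cocktail in both formats. The random lists carry the same shift, so a list is read from its percentile as well as from its median.

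The culture formats at 1 dpa were compared first in mouse. In mouse connective tissue-like cells, targets of the hypoxia-inducible factors (HIFs), the transcription factors that accumulate when oxygen is low, were lower at the air-liquid interface than in the plate. Glycolytic enzymes, mitotic genes and p53 targets were lower there as well. Genes of bone formation, of the fibrillar matrix and of the mitochondrial genome were higher at the interface. The differences in mitotic, p53, bone and matrix genes were smaller in the best-scoring clusters.

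The HIF target list had 0 of 34 measured members at least 1.5-fold higher and 29 lower, median log2 ratio -1.44, percentile 0. Adm, encoding the vasodilator peptide adrenomedullin, was at 1.79 [1.33 to 2.34] against 12.1 [10.95 to 13.3] CPM at the interface against the plate (log2 ratio -2.76). Ero1a, an oxidase that forms disulfide bonds in the endoplasmic reticulum, was at 36.9 [34.8 to 39.2] against 203 [198 to 208] CPM. Also lower were the transcriptional repressor Bhlhe40 (8.69 against 42.8 CPM), the glucose transporter gene Slc2a3 (24.3 against 111 CPM) and the angiogenic factor Vegfa (99.3 against 298 CPM). The list of glycolytic enzymes had 0 of 17 measured members at least 1.5-fold higher and 15 lower, median log2 ratio -1.196, percentile 0. Pfkp, a phosphofructokinase, was at 9.38 against 44.4 CPM, the aldolase Aldoa at 371 against 1347 CPM and the enolase Eno2 at 10.9 against 38.99 CPM. Of the oxygen sensors themselves, the prolyl hydroxylases Egln3 (log2 ratio -1.39) and Egln1 (-1.26) were lower, their relative Egln2 was higher (50.7 [48.1 to 53.3] against 34.6 [32.7 to 36.6] CPM), and Hif1a was level (0.00). The 13 transcripts of the mitochondrial genome were mostly higher (8 of 13 higher, 0 lower, median 0.64, percentile 100). Among them mt-Nd3, a subunit gene of respiratory complex I, was at 1191 against 207 CPM. The mitochondrial share is also a measure of cell quality, and all kept cells lie under 5%: 1820 of 5560 barcodes at the interface and 1234 of 5423 in the plate lay over it, and the kept cells had medians of 3.33% and 1.91%. With the own thresholds, up to 10%, the list median was 0.65, but a difference in cell or RNA quality between the libraries stays open. Nuclear genes of oxidative phosphorylation were higher by little more than the median of all genes (3 of 31 higher, 0 lower, median 0.23, percentile 97.9).

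Mitotic genes were lower at the interface (1 of 22 higher, 19 lower, median -1.06, percentile 0). These included the spindle checkpoint kinase gene Bub1 (4.78 against 19.5 CPM), the mitotic kinesin gene Kif11 (8.62 against 29.5 CPM) and Aurka (4.16 against 13.7 CPM). S-phase genes were not shifted (0 of 23 higher, 5 lower, median 0.05, percentile 14.6). The p53 targets were lower (0 of 15 higher, 8 lower, median -0.73, percentile 0). The pro-apoptotic gene Bbc3 was at 7.42 against 41.5 CPM and the stress gene Sesn2 at 3.57 against 7.82 CPM. The list of histone demethylases and Polycomb genes was lower by a smaller step (0 of 20 higher, 7 lower, median -0.42, percentile 0.0200). Kdm3a, which removes methyl groups from histone H3 lysine 9, was at 54.2 against 128 CPM and the Polycomb subunit gene Eed at 45.6 against 116 CPM. Wnt targets (1 of 15 higher, 5 lower, median -0.41, percentile 0.1), inflammatory signals (1 of 10 higher, 4 lower, median -0.48, percentile 1.83) and interferon-stimulated genes (2 of 14 higher, 4 lower, median -0.40, percentile 0.130) were lower too. Il11, a cytokine of the IL-6 family, was at 0.275 against 1.17 CPM (51.2% of UMIs in 1 cell) and the antiviral tetherin gene Bst2 at 17.3 against 84.3 CPM.

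Osteogenic genes were higher at the interface (6 of 7 higher, 0 lower, median 1.60, percentile 100). They included the osteoblast transcription factor genes Sp7 (4.604 [3.86 to 5.45] against 1.14 [0.816 to 1.55] CPM) and Runx2 (195 against 57.3 CPM), and Alpl, the phosphatase of mineralizing matrix (10.96 against 2.85 CPM). Much of this came from clusters 15 and 18, both mostly from the interface library, with 130 and 101 cells there and 5 and 15 in the plate. Without these clusters the list median was 0.56, Sp7 0.56, Runx2 0.78 and Alpl 0.44. Fibrillar matrix genes were higher (10 of 23 higher, 0 lower, median 0.55, percentile 99.99). They included the proteoglycan genes Vcan (526 against 234 CPM) and Lum (351 against 158 CPM). Tendon genes (5 of 8 higher, 1 lower, median 0.68, percentile 99.3) and muscle markers (8 of 10 higher, 0 lower, median 0.99, percentile 99.5) were higher as well. The latter include the muscle regulators Myog (6.29 against 1.77 CPM) and Myod1 (2.82 against 0.913 CPM) at low levels for cells that are not muscle. The limb patterning list as a whole was not shifted (4 of 25 higher, 4 lower, median 0.07, percentile 31.4), but its members differed in both directions. Hoxd13, which marks the hand and foot region, was at 0.344 [0.165 to 0.632] against 2.63 [2.12 to 3.22] CPM, Hoxa13 at 1.44 against 3.80 CPM, and the hedgehog target Gli1 at 23.4 against 6.22 CPM. Ccn2, a matrix-associated target of YAP, was lower (4.88 against 16.01 CPM), and Egr1, an immediate-early gene of ERK signalling, higher (248 against 106 CPM).

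The other lists stayed inside the range of the random lists in these cells. Their medians and percentiles were: oxygen sensing 0.05 (39.6), antioxidant genes 0.18 (60.3), AER genes 0.34 (78.0), wound epidermis 0.23 (56.8), basal keratinocytes -0.02 (23.2) and periderm 0.10 (34.5). For signalling and stress they were: contractile and YAP genes -0.01 (20.6), BMP targets -0.20 (2.71), ERK targets 0.28 (77.5), integrated stress response -0.05 (10.7), immediate-early and heat shock genes 0.13 (56.9), chondrogenesis 0.15 (52.8) and cholesterol synthesis 0.42 (95.1). For markers of other cell types they were: erythroid 0.50 (91.6), myeloid -0.35 (9.85), endothelial 0.70 (91.5) and Schwann cells 0.22 (49.8).

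By size of ratio alone, the highest genes at the interface included Rasal3, Adamts8, Cma2, Trp73 and Ak9. Each of these owed at least 95% of its UMIs to 1 cell (Rasal3 99.3%, Adamts8 96.3%, Cma2 97.9%, Trp73 97.53%, Ak9 99.3%), so these ratios describe single cells. The 6 lowest include Vmn1r54 and Slc22a20, without a UMI at the interface (at least 71.2-fold and at least 35.2-fold lower, 92.2% and 55.1% of UMIs in 1 cell). The others were Il22ra1 (ratio 0.0100 [0.00121 to 0.0366]), Abcb5 (ratio 0.0214 [0.00436 to 0.0635], 64.5% in 1 cell), Gpr179 (0.206 against 13.4 CPM, 63.8% in 1 cell) and Ly86 (1.86 against 62.6 CPM). Among genes detected in at least 10% of the cells of the higher library, a filter chosen after this was seen, the leading genes were the cation channel gene Trpc5 (67.6 against 10.8 CPM) and Lgi2 (23.9 against 3.74 CPM) on the higher side. On the lower side stood Ly86, the histone genes H3c11 (2.85 against 24.1 CPM) and H4c9 (13.9 against 101 CPM), and the stress gene Gadd45b (8.93 against 62.7 CPM). Different clusters filled the class. Clusters 0 and 1 held 26.5% and 18.8% of the plate's class, and clusters 2 and 6 17.3% and 14% of the interface's. Of these, cluster 0 scored below the median cluster for connective tissue (-0.42), and cluster 1 scored higher for tendon (1.08 against 0.56) and had a tendon marker among its top 10 genes but none of connective tissue. In the best-scoring clusters alone, medians were -1.22 for HIF targets and -1.16 for glycolysis, but only -0.30 for mitotic genes, -0.15 for p53 targets, 0.15 for fibrillar matrix and 0.10 for osteogenic genes, and the log2 ratios of Sesn2 (0.28) and Sp7 (-0.32) had the other sign.

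Mouse epithelial-like cells at 1 dpa were 26 and 75 (interface, plate). Their HIF target list was within the range of random lists (4 of 27 higher, 10 lower, median -0.28, percentile 4.09). Ero1a was at 14.5 against 45.1 CPM, the collagen hydroxylase gene P4ha1 at 65.1 against 203 CPM and Vegfa at 36.2 against 95.5 CPM. Over every kept cell the HIF target median was -1.28. With the own thresholds it was -1.01, from more epithelial-like cells (131 and 85 in the largest cluster). Proliferation genes were higher at the interface, both those of S phase (11 of 17 higher, 0 lower, median 0.89, percentile 99.99) and those of mitosis (13 of 14 higher, 0 lower, median 1.65, percentile 100). Of the interface cells, 9 lay in cluster 23 and held 51.03% of the class's UMIs, so that few cells weigh heavily; with each cell weighted equally the medians were 0.82 and 0.79. The mitotic median was 0.42 with the own thresholds and of the other sign, -0.83, over every kept cell, where the S-phase median was 0.0498. The replication helicase gene Mcm5 was at 50.7 against 8.58 CPM and Mki67 at 65.1 against 15.02 CPM. Cholesterol synthesis genes were higher (9 of 10 higher, 0 lower, median 1.62, percentile 100). Among them Idi1 was at 61.5 against 10.7 CPM. BMP targets were lower (0 of 7 higher, 6 lower, median -1.09, percentile 0.205, but a median of 0.20 with another low-count filter), while the 5 measured AER genes were within the random range (0 of 5 higher, 4 lower, median -0.98, percentile 2.56). The epithelial master regulator Trp63 was at 253 against 406 CPM. Matrix genes such as Lum (90.4 against 5.37 CPM) were higher in this class, in which they are not normally made (9 of 11 higher, 1 lower, median 1.97, percentile 100). Connective tissue markers together stood at 16.9% of their level in connective tissue-like cells at the interface and at 4.79% in the plate, so RNA or cells of connective tissue in this class differed between the libraries. Tex21, Hnf4aos, Zc2hc1c and the skin gene Ly6d had the highest ratios through 1 cell each, which held all of their UMIs, beside the skin genes Cstdc5 (2391 against 118 CPM, 86.4% of UMIs in 1 cell) and Lgals7 (474 against 76.2 CPM, 55.0%, and a log2 ratio of -0.12 with the own thresholds). Lowest were Kcnd2 (at least 12.2-fold), Sorbs2 (ratio 0.0207 [0.000521 to 0.117]) and Dnah8 (ratio 0.0291 [0.000730 to 0.165]). Next came Arg1 (ratio 0.0758 [0.00904 to 0.282]), Adamts18 (ratio 0.0793 [0.00945 to 0.296]) and Sema3a (32.6 against 263 CPM).

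The same pair of formats was compared in Xenopus at 1 dpa. In Xenopus connective tissue-like cells the HIF target, glycolysis, mitotic and histone demethylase lists were again lower at the air-liquid interface, and mitochondrially encoded transcripts were higher. Of the other lists, antioxidant and inflammatory genes were higher at the interface, and matrix, BMP target, heat shock and cholesterol synthesis genes lower. Differences from the mouse were not tested.

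The HIF target list had 1 of 31 measured members at least 1.5-fold higher and 18 lower, median log2 ratio -0.76, percentile 0. The gene ankrd37, a HIF target with ankyrin repeats, was at 1.09 [0.873 to 1.35] against 86.6 [84.4 to 88.8] CPM at the interface against the plate (log2 ratio -6.31). The oxygen-sensing prolyl hydroxylase gene egln3 was at 0.901 [0.704 to 1.14] against 10.7 [9.94 to 11.5] CPM (log2 ratio -3.57). The gene pfkfb3, whose product makes an activator of glycolysis, was at 39.6 [38.2 to 41.0] against 427 [422 to 432] CPM. The collagen hydroxylase gene p4ha2 followed (29.6 against 199 CPM), and vegfa was at 86.5 against 271 CPM. Among glycolytic enzymes (0 of 15 higher, 12 lower, median -0.96, percentile 0) the aldolase aldoc was at 2.33 against 18.6 CPM, the hexokinase hk1 at 6.41 against 41.5 CPM and the lactate dehydrogenase ldha at 17.4 against 92.5 CPM. Mitochondrially encoded transcripts (1 of 13 higher, 0 lower, median 0.45, percentile 100) and nuclear oxidative phosphorylation genes (0 of 36 higher, 0 lower, median 0.15, percentile 99.8) were higher by small steps. In the best-scoring clusters their medians were 0.20 and -0.0321, and the median mitochondrial share of kept cells was 1.95% and 1.23% (interface, plate). The oxygen sensing list was within the random range (0 of 16 higher, 5 lower, median -0.08, percentile 19.2). The histone demethylase and Polycomb list was lower (0 of 16 higher, 3 lower, median -0.27, percentile 0.0700). Here kdm3a was at 37.4 against 105 CPM and jarid2, a cofactor of Polycomb, at 339 against 605 CPM.

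Antioxidant genes were higher at the interface (9 of 17 higher, 0 lower, median 0.61, percentile 100). The metallothionein gene mt4 led them (22.8 [21.8 to 23.9] against 3.44 [3.02 to 3.90] CPM). The extracellular superoxide dismutase gene sod3 was at 2.54 against 1.03 CPM and the heme oxygenase gene hmox1 at 18.1 against 7.73 CPM. Inflammatory signals were higher (5 of 9 higher, 1 lower, median 0.78, percentile 100). These included the chemokine gene cxcl2 (1.78 against 0.530 CPM), the cytokine gene lif (12.8 against 4.26 CPM) and il1b (0.977 against 0.401 CPM), while il6 was lower (0.203 against 0.473 CPM). The list of immediate-early and heat shock genes was lower (0 of 16 higher, 3 lower, median -0.22, percentile 0.930). The largest differences among the genes named were those of heat shock genes outside this list: hsp30d, a small heat shock protein gene, was at 1.02 against 223 CPM, hsp30c at 0.457 against 39.7 CPM and the chaperone gene hsp70 at 1.69 against 295 CPM. Within the plate, hsp70 was at 1066 CPM in clusters 7, 11 and 19 together and at 67.1 CPM in the other connective tissue-like cells. Of the list itself, the cochaperone gene dnajb1 was at 5.52 against 24.7 CPM. BMP targets were lower (0 of 13 higher, 4 lower, median -0.32, percentile 0.190). The gene nog, for the BMP antagonist noggin, was at 7.18 against 26.9 CPM. Cholesterol synthesis genes were lower (0 of 16 higher, 7 lower, median -0.51, percentile 0), with msmo1 at 192 against 399 CPM. Matrix genes were slightly lower (0 of 21 higher, 4 lower, median -0.19, percentile 0.550), with the lysyl oxidase gene lox at 3.95 against 10.1 CPM. Chondrogenic genes were lower too (2 of 19 higher, 3 lower, median -0.23, percentile 1.59), although the cartilage proteoglycan gene acan was higher (90.3 against 40.2 CPM). Mitotic genes were lower by a small step (1 of 20 higher, 3 lower, median -0.37, percentile 0.0300). Amotl2, a target of YAP, was at 3.45 against 19.4 CPM, the tendon regulator scx at 21.2 against 60.9 CPM and the limb gene sall4 at 18.9 against 8.20 CPM.

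The highest ratios at the interface were those of slurp1l (ratio 35.8 [9.61 to 301], 59.3% of UMIs in 1 cell), cga (0.964 against 0.1004 CPM), slc11a1 (1.64 against 0.172 CPM) and scppa2 (108 against 12.98 CPM). They were followed by the secreted chaperone gene clu (118 against 14.4 CPM) and the drug-metabolizing cytochrome gene cyp3a4.2 (29.7 against 3.76 CPM). The lowest were hsp30d, hsp70, hsp30c, ankrd37, egln3 and pfkfb3, given above. Clusters 7 and 11, with almost no interface cells, held 13.3% and 12% of the plate's class, and clusters 8 and 5 held 11.3% and 11.1% of the interface's.

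In Xenopus epithelial-like cells the HIF target list was lower by a smaller step (3 of 27 higher, 9 lower, median -0.33, percentile 0). Connective tissue markers stood at 58.3% (interface) and 66.5% (plate) of their level in connective tissue-like cells, so this class holds connective tissue cells or RNA, or shares these genes. Cluster 20 (46.8% and 51.3% of cells) was at 7737 CPM, clusters 23 and 24 at 319 and 1863 CPM. Here egln3 was at 1.01 against 3.24 CPM and the mitophagy receptor gene bnip3 at 3.03 against 6.49 CPM. The HIF target median was -0.02 with each cell weighted equally and -0.85 over every kept cell. S-phase genes were lower at the interface (0 of 15 higher, 9 lower, median -0.92, percentile 0, but -0.12 with each cell weighted equally). Mitotic genes were lower too (0 of 12 higher, 4 lower, median -0.40, percentile 0.850, but 0.11 so weighted or with .S homeologs alone). The gene tyms, for thymidylate synthesis, was at 1.52 against 4.78 CPM and top2a, for the topoisomerase of dividing cells, at 3.79 against 14.3 CPM. Wound epidermis genes were higher (8 of 12 higher, 0 lower, median 0.80, percentile 100). They included the EGF receptor ligands areg (318 against 178 CPM) and ereg (91.0 against 40.3 CPM) and the fibronectin gene fn1 (21.2 against 8.88 CPM). Cholesterol synthesis (8 of 16 higher, 0 lower, median 0.56, percentile 100, but -0.40 over all kept cells) and stress response genes (5 of 15 higher, 0 lower, median 0.50, percentile 100) were higher, the latter with ddit3 at 115 against 45.1 CPM. Highest by ratio were npy (at least 26.6-fold), the neuropeptide gene tac1 (19.7 against 0.683 CPM, 57.7% of UMIs in 1 cell), and mt4 (16.7 against 0.854 CPM). Next came scppa2 (89.5 against 4.78 CPM, 96.9% of UMIs in 1 cell), the cytokine gene csf3 (55.6 against 3.76 CPM) and pmp2 (37.2 against 2.90 CPM). The lowest were arl11l.1 (2.78 against 36.7), hsp30d (1.26 against 16.4) and the keratin gene krt12.4 (9.86 against 106), and next the replication factor gene pclaf (2.27 against 19.1), hsp70 (2.78 against 21.9) and rnf182 (1.26 against 8.88), all in CPM.

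**Figure D1:**
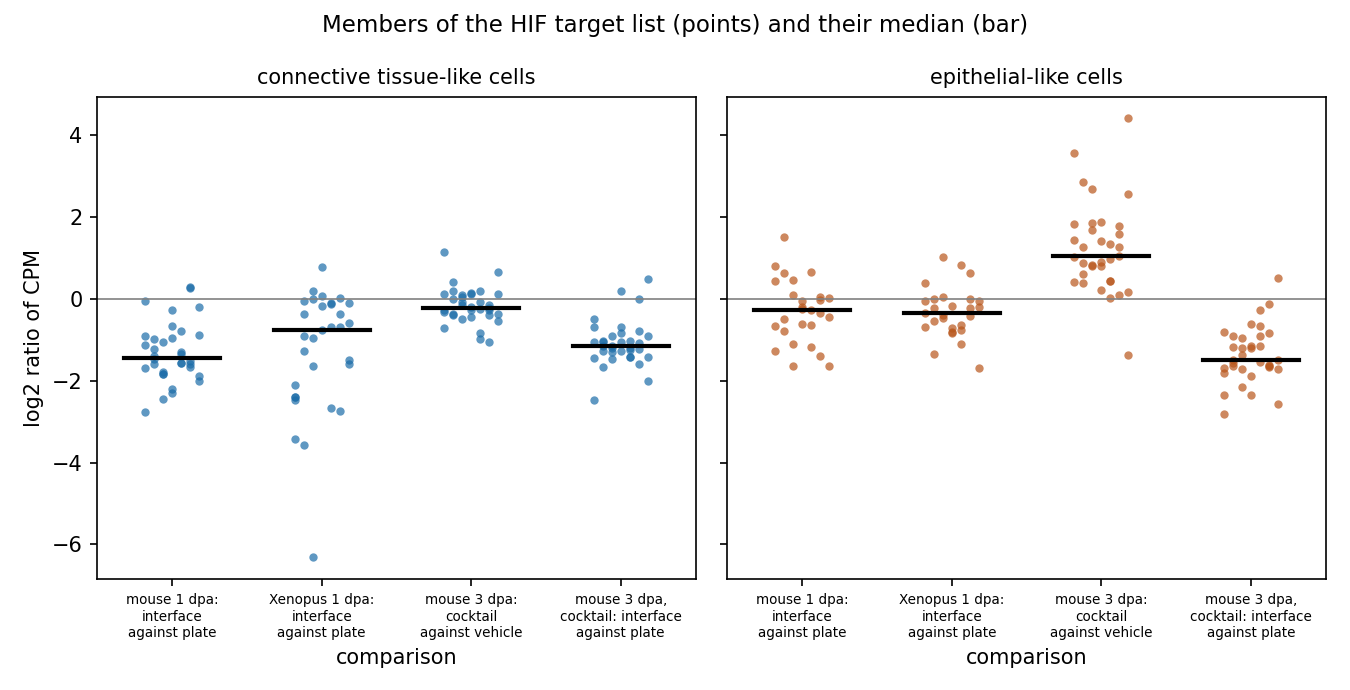
Log2 ratios of the members of the HIF target list (y axis) in the 4 comparisons (x axis), for connective tissue-like cells on the left and epithelial-like cells on the right; each point is 1 gene and each bar the median. The points lie below 0 in most panels where the interface is compared with the plate, and above 0 in epithelial-like cells with cocktail against vehicle.

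In mouse at 3 dpa the cocktail was compared with its vehicle in 96-well plates. In epithelial-like cells targets of the cocktail's 3 pathways, Wnt, BMP and ERK, were higher with cocktail. So were AER genes, wound keratins and HIF targets, and proliferation genes were lower. Over all kept cells, mostly of other classes, AER, HIF target and proliferation medians had the other sign. In connective tissue-like cells BMP and ERK targets were higher too, but proliferation genes were higher rather than lower, and fibrillar matrix genes were lower.

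Among epithelial-like cells, Wnt targets had 12 of 13 measured members at least 1.5-fold higher and 0 lower, median log2 ratio 3.79, percentile 100. These include the feedback inhibitor genes Wif1 (256 against 0.725 CPM), Nkd1 (202 against 1.45 CPM) and Notum (166 against 0 CPM). ERK targets (12 of 15 higher, 0 lower, median 2.54, percentile 100) included the ETS factor gene Etv4, which acts downstream of FGF (57.9 [45.3 to 72.9] against 2.18 [0.449 to 6.36] CPM), and the ERK phosphatase gene Dusp6 (89.2 against 5.08 CPM). BMP targets (8 of 9 higher, 0 lower, median 1.497, percentile 99.97) included the homeobox gene Msx2 (84.4 against 16.7 CPM) and Bambi, a decoy receptor (347 against 19.6 CPM). AER genes were higher (11 of 13 higher, 1 lower, median 2.002, percentile 100, but -0.12 over all kept cells). Bmp4 was at 225 [199 to 253] against 7.25 [3.48 to 13.3] CPM, the AER transcription factor gene Sp6 at 80.4 against 5.80 CPM, and Bmp2 at 124 against 0.725 CPM. HIF targets were higher with cocktail in these cells (25 of 34 higher, 1 lower, median 1.04, percentile 100). The carbonic anhydrase gene Car9 (61.9 against 2.90 CPM), Adm (112 against 9.43 CPM) and Egln3 (253 against 34.8 CPM) led them. Glycolysis was higher too (11 of 17 higher, 1 lower, median 0.71, percentile 99.9). Over every kept cell of the libraries, in place of epithelial-like ones, the HIF target median was -0.13. Nuclear oxidative phosphorylation genes were lower (0 of 31 higher, 12 lower, median -0.53, percentile 0.0450). Wound epidermis genes (12 of 17 higher, 1 lower, median 2.15, percentile 100) and periderm genes (12 of 16 higher, 1 lower, median 1.22, percentile 100) were higher. The cornified envelope gene Lor was at 2824 against 21.8 CPM (86.4% of UMIs in 1 cell) and Krt6b, a keratin of wounded skin, at 616 against 0 CPM. Mitotic genes were lower without exception (0 of 20 higher, 20 lower, median -2.92, percentile 0). The mitotic cyclin gene Ccnb1 was at 3.21 against 56.6 CPM. S-phase genes were lower as well (0 of 17 higher, 16 lower, median -1.11, percentile 0.160). Over all kept cells these medians had the other sign (mitotic 0.83, S-phase 0.54). The cell cycle inhibitor gene Cdkn1a was at 665 against 48.6 CPM, Ddit3 at 258 against 56.6 CPM and Hmox1 at 165 against 11.6 CPM (64.9% of UMIs in 1 cell). By size of ratio, the highest genes were Krt16 (ratio 1582 [437 to 13068]) and 5 genes without a UMI in the vehicle library. These were Slpi (at least 1035-fold), Crct1 (at least 995-fold, 64.4% of UMIs in 1 cell), Calm4 (at least 726-fold, 85.3%), Cnfn (at least 484-fold) and Flg (at least 411-fold), the last from 1 cell. Several of these belong to the cornified layer of skin. The lowest were Krt4 (at least 29.2-fold), Paqr6 (ratio 0.0272 [0.00554 to 0.0815]), Npas1 (at least 256-fold, from 1 cell) and Fam241a (8.04 against 261 CPM). The others, Pabpc1l (at least 28.9-fold, 96.9% of UMIs in 1 cell) and Capn11 (ratio 0.0122 [0.000305 to 0.0696], 98.9%), rested on single cells.

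In connective tissue-like cells the cocktail's pathways were again visible in BMP targets (9 of 14 higher, 0 lower, median 0.79, percentile 100), ERK targets (7 of 16 higher, 0 lower, median 0.53, percentile 100) and, less evenly, Wnt targets (6 of 15 higher, 5 lower, median 0.16, percentile 99.9, but -0.13 in the best-scoring clusters). Msx2 was at 21.5 [19.7 to 23.4] against 1.51 [0.975 to 2.22] CPM and its relative Msx1 at 19.7 against 2.23 CPM. Etv4 was at 34.1 against 4.58 CPM, and the secreted Wnt inhibitor genes Dkk1 at 51.9 against 5.003 CPM and Notum at 40.1 against 7.78 CPM. In contrast, Lgr5, a receptor for R-spondins (10.04 against 71.7 CPM), and Rspo2 (0.669 against 6.03 CPM) were lower. Proliferation genes were higher in S phase (13 of 23 higher, 0 lower, median 0.62, percentile 100) and in mitosis (19 of 22 higher, 0 lower, median 0.91, percentile 100). The mitotic kinase gene Plk1 was at 13.1 against 5.30 CPM and the ribonucleotide reductase gene Rrm2 at 31.3 against 10.7 CPM. Cartilage genes were lower (1 of 15 higher, 10 lower, median -1.24, percentile 0), though hardly in the best-scoring clusters (median -0.12). Matn4 was at 4.89 against 60.7 CPM and Col2a1, the main cartilage collagen, at 12.7 [11.3 to 14.2] against 47.8 [44.5 to 51.2] CPM. Fibrillar matrix genes were lower as a list (2 of 23 higher, 11 lower, median -0.47, percentile 0.110). Here elastin, Eln, was at 29.2 against 221 CPM, but tenascin C, Tnc, was higher (434 against 60.8 CPM). The tendon gene Tnmd was at 0.585 against 6.33 CPM, Ccn2 at 8.15 against 42.1 CPM, and the chemokine gene Cxcl12 at 9.07 against 61.4 CPM. HIF targets were not shifted (2 of 34 higher, 4 lower, median -0.21, percentile 48.4), although Adm was higher (35.7 against 16.2 CPM). Glycolysis (2 of 17 higher, 0 lower, median 0.11, percentile 99.0), antioxidant (8 of 20 higher, 3 lower, median 0.20, percentile 99.98) and p53 lists (4 of 15 higher, 0 lower, median 0.38, percentile 100) were higher by small steps. So were inflammatory (5 of 12 higher, 2 lower, median 0.36, percentile 99.6) and osteogenic lists (4 of 9 higher, 2 lower, median 0.36, percentile 99.4), the latter with Spp1, osteopontin, at 98.3 against 14.04 CPM but Alpl at 1.51 against 6.63 CPM. Of these medians, glycolysis (-0.11) and antioxidant genes (-0.0924) had the other sign without clusters mostly from 1 library. Inflammatory (-0.28) and osteogenic genes (-0.74, Spp1 -0.33) had it with cells by the own thresholds. Interferon-stimulated genes were lower (1 of 12 higher, 7 lower, median -0.63, percentile 1.55), as were erythroid markers (0 of 7 higher, 6 lower, median -2.77, percentile 0).

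The wound epidermis list was higher in connective tissue-like cells too (13 of 22 higher, 2 lower, median 2.41, percentile 100), through the matrix protease genes Mmp13, without a UMI in the vehicle library (at least 56.2-fold), and Mmp9 (109 against 8.44 CPM). Keratins such as Krt6a were higher as well (4.14 against 0.0603 CPM), beside 2097 against 76.1 CPM in epithelial-like cells of the same libraries. Among the highest ratios with cocktail were those of Flt3 (at least 95.3-fold), Platr4 (at least 50.2-fold) and the desmosome gene Pkp1 (18.1 against 0.362 CPM), with 98.8%, 99.1% and 77.2% of their UMIs in 1 cell. The others were Dlx2 (ratio 112 [30.9 to 932]), the chemokine gene Ccl12 (ratio 193 [34.3 to 7646]) and Mmp13. The lowest were Lcn2 (at least 50.9-fold), Jakmip1 (0.251 against 25.6 CPM), Sv2b (ratio 0.0151 [0.00307 to 0.0450]), Cntnap5b (0.585 against 32.5 CPM), Oprk1 (0.209 against 11.6 CPM) and Aoah (0.209 against 10.6 CPM, 72.7% of UMIs in 1 cell). Among genes in at least 10% of cells, the transcription factor gene Tfap2c (42.0 against 0.904 CPM) and Pla2g7 (39.4 against 1.99 CPM) led the higher side. The growth factor gene Fgf7 (2.26 against 37.01 CPM) and Ogn (14.1 against 222 CPM) followed Jakmip1 on the lower. The class was filled by clusters 9 and 12 in the vehicle library (24.8% and 23.2%, mostly from this library) and by clusters 0 and 3 with cocktail (30.9% and 23.3%).

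With the cocktail present in both, the air-liquid interface was then compared with the 96-well plate at 3 dpa, to see whether the format alters the response. HIF targets and glycolytic genes were lower at the interface in both connective tissue-like and epithelial-like cells, and mitochondrially encoded transcripts higher. Targets of p53 were lower in both classes and BMP targets in connective tissue-like cells, where inflammatory and myeloid genes were higher. Epithelial-like cells at the interface carried more proliferation transcripts and fewer transcripts of the periderm and cornified layers.

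In connective tissue-like cells the HIF target list had 0 of 34 measured members at least 1.5-fold higher and 30 lower, median log2 ratio -1.16, percentile 0. Ddit4, an mTOR inhibitor induced by low oxygen, was at 31.4 [29.96 to 32.9] against 175 [169.7 to 180.4] CPM and the carbonic anhydrase gene Car9 at 5.60 against 22.4 CPM. Egln3 was at 21.6 [20.4 to 22.9] against 68.04 [64.8 to 71.4] CPM and Ndrg1 at 30.1 against 90.6 CPM. Glycolysis was lower (0 of 17 higher, 16 lower, median -1.07, percentile 0). Eno1 was at 124 against 399.5 CPM and Pfkp at 24.3 against 76.7 CPM. Mitochondrially encoded transcripts were higher (6 of 13 higher, 0 lower, median 0.50, percentile 99.95), with the same reserve as at 1 dpa (median share of kept cells 3.36% and 1.74%). The chromatin list was lower (0 of 20 higher, 5 lower, median -0.26, percentile 0.200), with Kdm3a, itself a HIF target, at 51.5 against 106 CPM. The heme oxygenase gene Hmox1 was far lower (2.47 [2.08 to 2.92] against 38.9 [36.4 to 41.4] CPM), and the heat shock gene Hspa1a lower (2.17 against 9.28 CPM). Targets of p53 were lower (0 of 15 higher, 12 lower, median -1.51, percentile 0). The pro-apoptotic gene Bax was at 5.40 against 113 CPM and Sesn2 at 3.23 against 16.6 CPM. The integrated stress response was lower (0 of 16 higher, 9 lower, median -0.68, percentile 0), with Trib3 at 2.97 against 8.11 CPM. BMP targets (1 of 14 higher, 9 lower, median -0.85, percentile 0) and Wnt targets (1 of 16 higher, 11 lower, median -0.84, percentile 0) were lower, the latter as at 1 dpa. Msx2 was at 2.19 against 21.5 CPM, Notum at 9.20 against 40.1 CPM and noggin, Nog, at 3.98 against 12.3 CPM. ERK targets were level (1 of 16 higher, 4 lower, median 0.01, percentile 57.9), and Lgr5 was higher (54.3 against 10.04 CPM), as was the limb bud mesenchyme signal Fgf10 (43.9 against 21.0 CPM). Hoxd13 was lower (0.480 against 2.84 CPM), as at 1 dpa.

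Inflammatory signals were higher at the interface (9 of 13 higher, 1 lower, median 0.84, percentile 99.98). The neutrophil-attracting chemokine genes Cxcl5 (19.9 against 1.59 CPM) and Cxcl1 (17.02 against 3.55 CPM) led them, beside Ccl2 (25.5 against 6.19 CPM). Myeloid markers in these cells were higher as well (7 of 8 higher, 0 lower, median 1.89, percentile 100, but -0.0994 over all kept cells). These included the complement gene C1qa (1.01 against 0.125 CPM), which connective tissue does not normally make, in libraries with 80 and 20 myeloid-like cells. Osteogenic genes were higher (5 of 9 higher, 1 lower, median 0.84, percentile 99.99, but 0.34 without clusters mostly from 1 library and -0.38 in the best-scoring clusters). Ibsp, a bone matrix protein gene, was at 74.8 against 2.01 CPM and Alpl at 8.38 against 1.51 CPM. Chondrogenic (6 of 16 higher, 2 lower, median 0.36, percentile 99.3, with finer clusters -0.0180) and cholesterol synthesis genes (8 of 16 higher, 0 lower, median 0.59, percentile 100) were higher, and the tendon gene Tnmd was at 7.53 against 0.585 CPM. Contractile genes were lower (0 of 17 higher, 7 lower, median -0.41, percentile 0.0100), with Tagln at 46.2 against 175 CPM. Mitotic genes were slightly higher (2 of 22 higher, 0 lower, median 0.23, percentile 99.5), but not with finer clusters (median -0.0385) or in the best-scoring clusters (-1.39). Basal keratinocyte (0 of 9 higher, 6 lower, median -0.92, percentile 0.650) and wound epidermis genes (2 of 22 higher, 10 lower, median -0.44, percentile 1.14) were lower. By size of ratio, the highest genes were the chemokine gene Ccl5 (at least 91.5-fold), Sycp2l (at least 40.1-fold), the acute phase gene Saa3 (26.3 against 0.460 CPM), Lyz2, a lysozyme of myeloid cells (ratio 45.3 [15.4 to 221]), Ibsp and Ecrg4 (21.2 against 0.627 CPM). The lowest were Prss22 (ratio 0.00410 [0.000494 to 0.0150]), Atp2c2 (0.124 against 21.3 CPM), and 4 genes with most of their UMIs in 1 cell. The latter were Platr4 (ratio 0.00196 [0.0000493 to 0.0110], 99.1%), Myadml2os (0.124 against 14.5 CPM, 93.9%), Fgr (0.142 against 11.3 CPM, 96.3%) and Cmklr2 (0.107 against 8.36 CPM, 90%). Among genes in at least 10% of cells, Steap4 (14.7 against 1.13 CPM) led the higher side and Bst2 (1.79 against 76.4 CPM) the lower. At the interface the class was filled by clusters 1, 4 and 0 (23.4%, 18.8% and 16.1%), of which cluster 4 came mostly from this library, and in the plate by clusters 0, 3 and 2. Within clusters with cells of both libraries the HIF target median ran from -1.58 to 0.08, and in clusters 0 and 3 it was 0.08 and 0.04.

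In epithelial-like cells the HIF target list was lower at the interface (0 of 34 higher, 31 lower, median -1.49, percentile 0). Ddit4 was at 47.6 [34.9 to 63.5] against 333 [301 to 366] CPM, Car9 at 10.4 against 61.9 CPM and Adm at 21.7 against 112 CPM. Glycolysis was lower likewise (0 of 16 higher, 15 lower, median -1.31, percentile 0). With cells chosen by the own thresholds the HIF target median was -2.39. S-phase genes (19 of 20 higher, 0 lower, median 1.92, percentile 100) and mitotic genes (12 of 13 higher, 0 lower, median 1.43, percentile 100) were higher. Mcm7 was at 71.4 against 6.43 CPM and Mki67 at 28.0 against 4.82 CPM. Periderm genes were lower (1 of 15 higher, 11 lower, median -2.94, percentile 0). Lor was at 54.9 against 2824 CPM (86.4% of UMIs in 1 cell) and Sbsn at 24.9 against 1636 CPM. AER genes were lower (1 of 13 higher, 9 lower, median -0.96, percentile 0.0250). The limb ectoderm gene En1 was at 6.21 against 42.6 CPM and Sp6 at 25.9 against 80.4 CPM. BMP targets were lower (2 of 9 higher, 5 lower, median -0.96, percentile 0.210, but 0.0730 with thinned cells), with Bambi at 31.1 against 347 CPM. Wnt targets (3 of 13 higher, 4 lower, median 0.01, percentile 29.7) and ERK targets (4 of 15 higher, 4 lower, median -0.27, percentile 5.88) were within the random range. Targets of p53 were lower (0 of 12 higher, 10 lower, median -1.25, percentile 0). Shh, which encodes a hedgehog morphogen, was higher (75.6 against 16.9 CPM), and Cdkn1a lower (183 against 665 CPM). By size of ratio, the highest genes were Kcnh7 (at least 79.5-fold, 50.3% of UMIs in 1 cell), Serpinb3b (at least 51.1-fold, 69.7%), the linker histone gene H1f5 (172 against 3.21 CPM), Sncaip (ratio 50.3 [16.8 to 247]), Dcn (125 against 4.02 CPM) and Wnt10b (ratio 21.9 [7.09 to 109.7]). Dcn is a connective tissue gene, seen here in 32.3% of interface cells, and fibrillar matrix genes were higher as a list (11 of 18 higher, 4 lower, median 0.78, percentile 99.8). Connective tissue markers together were at 576 and 369 CPM in this class (interface, plate), so RNA or cells of connective tissue were part of it. Of the 6 lowest, 5 were genes of the cornified layer. These were Flg (at least 288-fold), Lce3c (at least 236-fold), Lce3e (at least 178-fold), Lce3f (ratio 0.00130 [0.0000330 to 0.00728]) and Crct1 (10.4 against 2165 CPM). Each leaned on 1 plate cell, which held all Flg UMIs and 66.3%, 97.2%, 89.4% and 64.4% of the others' UMIs. Lowest of all was the protease inhibitor gene Slpi (6.21 against 2252 CPM).

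**Figure D2:**
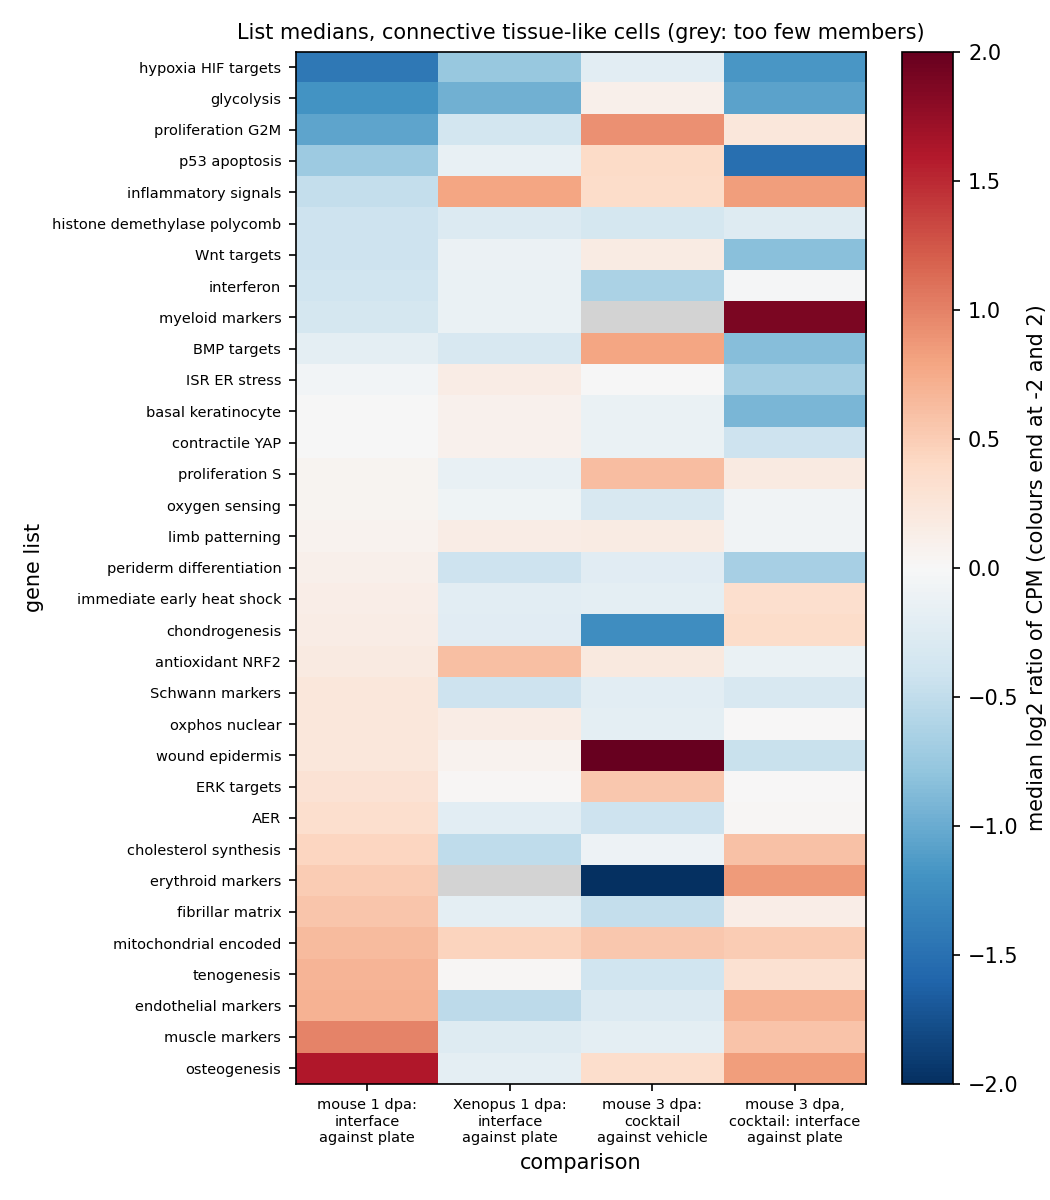
Median log2 ratio (colour; blue lower, red higher) of each gene list (y axis) in connective tissue-like cells in the 4 comparisons (x axis). The HIF target and glycolysis lists are blue in the 3 columns that set the air-liquid interface against the plate, and the list of mitochondrially encoded transcripts is red in them; most other lists differ in sign between these columns.

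The genes that sense oxygen were read in all 7 libraries. In connective tissue-like cells Egln3, itself a HIF target, was lower at the air-liquid interface in every pair: 11.3 [10.1 to 12.6] against 29.8 [28.0 to 31.7] CPM in mouse at 1 dpa, 0.901 [0.704 to 1.14] against 10.7 [9.94 to 11.5] CPM in Xenopus. With cocktail at 3 dpa it was at 21.6 against 68.04 CPM, beside 51.4 CPM with vehicle. Egln1, the main prolyl hydroxylase acting on HIF, was lower in mouse at 1 dpa (111 against 266 CPM) and at 3 dpa (121 against 178, vehicle 270.3), but not in Xenopus (28.2 [27.1 to 29.4] against 24.001 [22.9 to 25.2]). Egln2 went the other way: it was higher in mouse at 1 dpa, as given above, and at 3 dpa with cocktail (41.4 against 33.6, vehicle 41.7), and lower in Xenopus (14.3 [13.4 to 15.1] against 31.2 [29.9 to 32.6]). Hif1a mRNA, whose protein rather than transcript is controlled by oxygen, was at 124 against 124 CPM in mouse and 114 [111 to 116] against 161 [158 to 164] CPM in Xenopus at 1 dpa. At 3 dpa it was at 88.2, 81.8 and 112 CPM (cocktail at the interface, cocktail in the plate, vehicle). Its partner Arnt was lower at the interface in mouse at 1 dpa (79.5 against 141 CPM). Among epithelial-like cells at 3 dpa Egln3 was highest with cocktail in the plate (253 CPM, against 81.8 at the interface and 34.8 with vehicle).

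**Figure D3:**
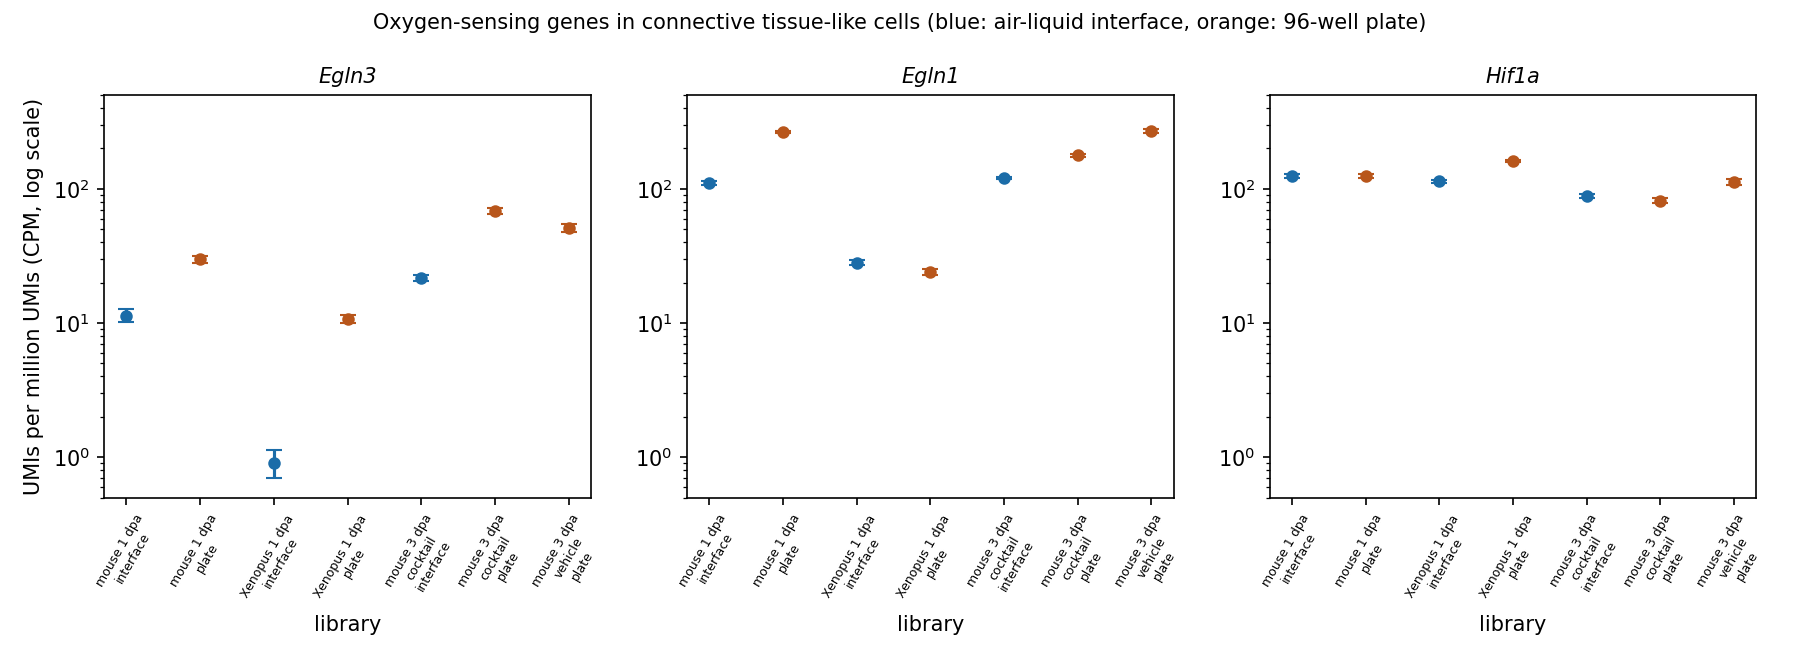
Expression of Egln3, Egln1 and Hif1a (y axis, CPM on a log scale) in connective tissue-like cells of the 7 libraries (x axis); each point is 1 library and each bar its 95% Poisson interval. Egln3 is lower at the air-liquid interface than in the matching plate in all 3 pairs, whereas Hif1a differs less between formats than Egln3 does.

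Fgf8, the signal that defines a working AER, was counted in epithelial-like cells, with mouse cells thinned to 500 UMIs and Xenopus cells to 1500. At 500 UMIs no mouse epithelial-like cell was positive, but so few UMIs would hardly hold a transcript of this level, so that count is not read. Without thinning, Fgf8 was found in 2 of 112 epithelial-like cells with cocktail in the plate (20 UMIs, 16.1 CPM [9.82 to 24.8]). No UMI was found in the epithelial-like cells of the other mouse libraries. That allows shares of cells with a UMI of up to 13.2% and 4.8% at 1 dpa (interface, plate) and 3.52% and 5.52% at 3 dpa (vehicle, cocktail at the interface), and does not limit the cells that express the gene. Connective tissue-like cells held Fgf8 as well: unthinned, 0.581% of them had a UMI with cocktail in the plate (0.627 CPM), and 6.88% and 5.50% in mouse at 1 dpa (interface, plate; 8.04 and 6.17 CPM). In the plate at 1 dpa this level lies above the upper limit in epithelial-like cells (3.96 CPM), so it is not RNA spread evenly over all cells. In Xenopus the thinned epithelial-like share was 0.346% at the interface and 0.592% in the plate, below the connective tissue-like shares of 1.01% and 2.002%, as were the unthinned levels (2.53 against 6.49 CPM at the interface, 3.41 against 14.2 CPM in the plate). Median depths before thinning were 12955.0 and 18993.0 UMIs in Xenopus epithelial-like cells, and 12817.0 and 10929.0 in connective tissue-like ones. Unthinned, 10 of 293 and 10 of 339 Xenopus epithelial-like cells had a UMI, again smaller shares than in connective tissue-like cells (5.80% and 9.98%). Whether few epithelial-like cells express Fgf8 at a low level cannot be read at this depth.

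Cell class shares differed between libraries in ways that a single library per group cannot tie to the culture. At 1 dpa the direction in mouse depended on the setting. Chondrocyte-like cells made up 8.04% [6.93 to 9.27] at the interface against 13.4% [12.2 to 14.7] in the plate, but 11.7% against 7.98% at resolution 0.5 and 9.37% against 5.47% with the own thresholds. The lower share at the interface came from cluster 8, with 220 plate and 9 interface cells and no chondrocyte marker among its top genes. Epithelial-like cells made up 1.202% [0.787 to 1.76] against 2.495% [1.97 to 3.12], but 4.82% against 3.24% with the own thresholds. In Xenopus, chondrocyte-like cells made up 8.12% [7.53 to 8.74] at the interface against 10.4% [9.76 to 11.1] in the plate at 1 dpa. The epithelial-like share was 1.40% [1.08 to 1.78] at the interface against 3.79% [3.13 to 4.55] in the plate with cocktail at 3 dpa. At 3 dpa tendon-like cells were 210 in number with cocktail at the interface, 4 with cocktail in the plate and 1 with vehicle, and muscle-like cells 334, 139 and 58. At resolution 0.5 no cluster was named tendon. Chondrocyte-like cells, in the order of the tendon-like ones, numbered 47, 4 and 97. No kept cell had more than 6000 genes, a limit that 29.9% of barcodes of the mouse interface library at 1 dpa exceeded against 15.2% of the plate's, so shares refer to the cells that remained.

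Whether the format acts alike across species was also asked gene by gene, with the log2 ratios of connective tissue-like cells at 1 dpa. Across 9931 genes measured in both species, Pearson's r was 0.07, Spearman's rho 0.06, and 52.5% of genes had the same sign. Between 1 dpa and 3 dpa with cocktail in mouse, r was 0.37 and rho 0.39 across 15071 genes, with 63.4% of one sign. In epithelial-like cells r was -0.06 between species (2986 genes) and 0.31 between days in mouse (3666 genes). These are correlations across genes, and genes are not independent replicates. Of the gene lists, 4 lay outside the random range in the same direction in connective tissue-like cells in all 3 comparisons of interface and plate: HIF targets, glycolysis and the histone demethylase and Polycomb list were lower, and mitochondrially encoded transcripts, also a measure of cell quality, higher.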

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

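Of the tests in this part, those with own thresholds for cells and with thinned cells on the HIF target list, the median over clusters, the share of cells with a single gene, and the mitochondrial share were chosen after the result was seen.

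Some lists went opposite ways under the same contrast in different groups; with 1 library per group these differences were not tested. In connective tissue-like cells at 1 dpa, the fibrillar matrix median for interface against plate was 0.55 in mouse (0.15 in clusters that scored highest for connective tissue) and -0.19 in Xenopus, and the median of inflammatory signals -0.48 and 0.78. Between 1 dpa and 3 dpa with cocktail in mouse, the medians were -1.06 and 0.23 for mitotic genes (the latter -0.0385 at resolution 2, and -0.30 and -1.39 in clusters that scored highest for connective tissue) and -0.48 and 0.84 for inflammatory signals. For the mitotic genes at 1 dpa an effect of the submitters' ceilings stays open. In epithelial-like cells at 1 dpa, S-phase genes were at 0.89 in mouse and -0.92 in Xenopus, and mitotic genes at 1.65 and -0.40. The Xenopus mitotic median was 0.11 with each cell weighted equally and with .S homeologs alone. The mouse one was -0.83 over all kept cells, which are mostly connective tissue-like.

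The lower HIF targets at the interface were weighed first. Ceilings on genes and UMIs in the submitters' cell set are argued against, since with cells chosen by own thresholds the connective tissue-like median nearer 0 of the mouse comparisons was -1.35. Unequal depth is argued against as well, since after thinning the median nearest 0 of the 3 comparisons was -0.79. A different mix of clusters stays open, since the median over clusters of within-cluster medians, -0.88 or below in each comparison, counts all clusters alike. Of the 28 clusters with enough cells of both libraries, 17.9% had medians at or above -0.3. Clusters 0 and 3 at 3 dpa (0.08 and 0.04) held 30.9% and 23.3% of the plate's class. At 1 dpa in mouse the medians nearest 0 were those of clusters 1, 0 and 5 (-0.13, -0.37 and -0.37), which held 18.8%, 26.5% and 10.1% of the plate's class. A candidate explanation is more oxygen at the interface, which would lower HIF activity in both species. Oxygen was not measured, and format and library cannot be told apart.

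The next pattern is cells with at least 20 UMIs (10 if thinned) of 1 rare gene, seen in under 1% of connective tissue-like cells. In mouse they made up 10.1% [8.86 to 11.5] in the plate against 4.79% [3.81 to 5.92] at the interface at 1 dpa, and 5.85% against 1.82% with cocktail at 3 dpa (vehicle 3.03%). In Xenopus they were 0.509% and 0.655%. Depth and the submitters' ceilings are argued against, since the smaller ratio of plate to interface over both days was 2.06 after thinning and 2.07 with own thresholds. Cells or RNA of another type joined to the cell are argued against because most such cells held a single gene of this kind, 61.3% in the mouse library with the lowest share. Amplification of single molecules could not be examined without reads and stays open, as does a biological cause such as transcription released at random loci in single cells, which was not tested. Through this pattern some leading ratios, as of Rasal3, Flt3 and Platr4, describe single cells.

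The last pattern is a subset of Xenopus plate cells with high heat shock genes: clusters 7, 11 and 19, the last unnamed, with 1978 cells, 22.997% of the plate's, against 2 of 7931 at the interface. Against the other connective tissue-like plate cells, hsp30d was at 850.0 and 38.97 CPM, ankrd37 at 238 and 48.6 and vegfa at 562 and 195, and the HIF target median was 0.42. The median of 12 immediate-early genes, -0.86, argues against a stronger response of these genes to dissociation, not against its other effects. Leaked cytoplasm is argued against by a mitochondrial share 0.328 times that of the other cells (0.540% against 1.65%). The subset also held fewer UMIs (median 8431 against 11977), so lower RNA content or other damage stays open. As a hypothesis, the heat shock and HIF target levels may mark oxygen-poor cells deep in the explant, which tissue position would have to test. An event in 1 explant or 1 well stays open too.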

How the results depend on the processing

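Of the tests in this part, those without clusters mostly from 1 library, with only the clusters that scored highest for connective tissue, without the highest doublet scores and with genes in at least 10% of cells were chosen after the data were seen, as were the 12 epithelial lists that were recomputed. Over all settings, 2086 list medians stayed within the interval of the reported value, 117 moved out of it with the same sign or from a median not called, and 29 changed sign; for named genes these numbers were 2029, 527 and 4.

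The HIF target median of connective tissue-like cells kept its sign in every setting run for the comparisons of interface and plate. It ran from -1.64 to -1.22 in mouse at 1 dpa, from -0.93 to -0.63 in Xenopus, and from -1.35 to -0.87 at 3 dpa, of which the lowest, with own thresholds, and the highest, with only the clusters that scored highest for connective tissue, lay beyond the interval of the reported value. For cocktail against vehicle it ran from -0.41 to 0.03. The correlations with genes of at least 200 UMIs were 0.09 between species and 0.41 between days in connective tissue-like cells (Pearson's r).

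In epithelial-like cells it moved more. With own thresholds it was -1.01 in mouse at 1 dpa and -2.39 with cocktail in both formats. Over all kept cells, which are mostly connective tissue-like by construction, it was -1.28 in mouse at 1 dpa, -0.85 in Xenopus and -0.13, of the other sign, for cocktail against vehicle. With each cell weighted equally it was -0.0230 in Xenopus; the cause was not tested. The Xenopus Fgf8 share of epithelial-like cells was 2.95% (plate) and 3.41% (interface) without thinning, from more UMIs per cell by construction, and with at least 2 UMIs 1.47% (plate) and 0.00% (interface).

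The medians that changed sign over all kept cells were, for cocktail against vehicle in epithelial-like cells, mitotic genes (0.83), S-phase genes (0.54), AER genes (-0.12) and cholesterol synthesis (-0.0736). The others were cholesterol synthesis in Xenopus (-0.40) and mitotic genes in mouse at 1 dpa (-0.83), both in epithelial-like cells, and, with cocktail in both formats in connective tissue-like cells, the markers of myeloid (-0.0994), muscle (-0.37) and endothelial cells (-0.22). Here the class itself is replaced, which by construction brings in the other cells. With own thresholds, osteogenic genes (-0.74), inflammatory signals (-0.28) and Spp1 (-0.33) changed sign for cocktail against vehicle in connective tissue-like cells, and Lgals7 (-0.12) in mouse epithelial-like cells at 1 dpa; the cause was not tested. With thinned cells, periderm (1.11) and basal keratinocyte genes (0.62) changed sign in mouse epithelial-like cells at 1 dpa, and BMP targets (0.0730) with cocktail in both formats, where thinning leaves fewer UMIs per gene. With each cell weighted equally these were periderm genes in mouse (0.73) and mitotic genes in Xenopus (0.11), both in epithelial-like cells; the latter also changed sign with .S homeologs alone (0.11). At resolution 0.5, erythroid markers (-0.68), and at resolution 2, chondrogenic (-0.0180) and mitotic genes (-0.0385) changed sign for cocktail in both formats, and at resolution 2 also inflammatory signals for cocktail against vehicle (-0.54), all in connective tissue-like cells; the cause was not tested. Without clusters mostly from 1 library, antioxidant (-0.0924) and glycolytic genes (-0.11) changed sign for cocktail against vehicle in connective tissue-like cells, and with another low-count filter BMP targets did in mouse epithelial-like cells at 1 dpa (0.20), with members of fewer UMIs by construction. With only the clusters that scored highest for connective tissue, nuclear oxidative phosphorylation genes in Xenopus (-0.0321), Wnt targets for cocktail against vehicle (-0.13), mitotic (-1.39) and osteogenic genes (-0.38) for cocktail in both formats, and Sesn2 (0.28) and Sp7 (-0.32) in mouse at 1 dpa changed sign; the cause was not tested.

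No paired analysis was possible because each group is 1 library. Own thresholds were not run for Xenopus. Scrublet called 2 and 3 mouse cells at 1 dpa (plate, interface), 2, 0 and 0 at 3 dpa (vehicle, cocktail in the plate, cocktail at the interface), and 5 and 3 in Xenopus (plate, interface), where its calls were not removed. With so few cells the mouse removal is no test of doublets; the totals above contain 134 list medians and 206 named genes from it, none of which moved. Single genes were not recomputed over all kept cells or with the other low-count filter. Of class shares, 70 of 281 lay outside the interval of the reported share, among them the mouse chondrocyte-like and epithelial-like shares at 1 dpa with own thresholds; the cause was not tested.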

Other observations

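Some lists were not described in the comparisons above. In mouse connective tissue-like cells with cocktail, some markers of other cell types were higher at the interface: muscle (5 of 10 higher, 0 lower, median 0.57, percentile 98.6), endothelial (4 of 7 higher, 2 lower, median 0.69, percentile 97.9) and erythroid ones (5 of 7 higher, 0 lower, median 0.85, percentile 99.7, but a median of -0.68 at resolution 0.5). In epithelial-like cells with cocktail against vehicle, p53 targets (8 of 12 higher, 0 lower, median 0.74, percentile 99.8), immediate-early and heat shock genes (9 of 16 higher, 0 lower, median 1.04, percentile 99.99) and inflammatory signals (4 of 4 higher, 0 lower, median 1.998, percentile 99.8) were higher. Interferon-stimulated genes were lower (0 of 5 higher, 5 lower, median -1.74, percentile 0.825). Contractile genes were lower in the epithelial-like cells with cocktail (2 of 15 higher, 8 lower, median -0.74, percentile 0.520), among them the myosin light chain gene Myl9 (9.64 against 76.1 CPM).

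Some genes seen in at least 10% of the plate's connective tissue-like cells with cocktail differed by far between interface and plate. Bst2 was at 1.79 against 76.4 CPM and Isg15, a ubiquitin-like protein gene induced by interferon, at 4.26 against 32.6 CPM. Another interferon-stimulated gene, Rsad2, was higher (3.87 against 0.167 CPM, seen in 1.57% of interface cells). Raly, an RNA-binding protein gene, was at 12.3 against 135 CPM (59.9 against 65.2 CPM at 1 dpa). Bax was at 5.40 against 113 CPM (33.2 against 39.4 CPM at 1 dpa). Of the mouse heat shock genes, Hspa1a and Hspa1b were lower at the interface on both days: Hspa1a was at 4.78 against 28.8 CPM at 1 dpa and 2.17 against 9.28 CPM with cocktail at 3 dpa. Hspa1b was at 3.75 against 19.8 CPM and 1.88 against 7.15 CPM. Hspb1 was lower too (log2 ratios -0.76 and -1.66), but others differed little at 1 dpa and 3 dpa, by log2 ratios of -0.03 and -0.10 for Hspa8, -0.08 and -0.15 for Hsph1, and -0.27 and -0.11 for Dnajb1.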
